A study of Homo sapiens with 2 samples.

How the data were processed

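Total RNA of SNU216, an established human gastric cancer cell line, was measured on Illumina BeadChip expression arrays with biotin-labelled cRNA, per the labels. The 2 arrays form 2 groups of 1 array each by their titles: a control and a TEAD4 knockdown. The control cells carried a non-silencing short hairpin RNA. Nothing in the labels gives the number of hairpins, the time after their delivery or a second culture.

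The deposited probe intensity values of the non-normalized table are on a linear scale. The table itself shows that a background level had already been subtracted, since 12861 of 47323 probes on the control array and 12895 on the knockdown array are below 0. A detection p-value per probe and array is deposited beside each signal, per the file headers. A further deposited intensity table holds values on a linear scale that had been quantile normalized: the sorted values of its 2 columns differ by at most 0.00186 on the log2 scale, and their medians are 118.7 and 118.7. Within each array its rank order equals that of the non-normalized signals (Spearman correlation 1). Its values are not centred and 1-colour signals have no direction. Its common distribution lies above the mean of the 2 sorted deposited signals by a median of 100.7 and by up to 4694, so it is not these 2 arrays plus a constant, and what it was normalized to is unknown. The software, its version and the form of the background subtraction are not given in the sources used here.

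Normalized log2 signals were computed from the non-normalized signals with the neqc function of limma 3.58.1 in R 4.3.3, which corrects the background with a normal-exponential model whose background is inferred from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. The plan had been to leave out the background step if the signals were already background-subtracted. The step was kept, because values below 0 have no logarithm and because the result does not depend on a subtracted constant: adding 100 to every signal moved no log2 difference by more than 3.6e-15. An alternative without this step was added after the data had been seen. All differences are the knockdown array minus the control array, so positive values are higher in the knockdown. The offset pulls fold changes of dim probes towards 1.

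Gene symbols came from the platform annotation. It gives 1 symbol for 30113 probes, several symbols for 8 and does not list 17202. Of the 30113 probes, 30074 matched a gene of the RefSeq table for GRCh38.p14 by Entrez identifier, 0 symbols changed, and 39 kept the annotation's symbol. No genome build is stated for the probes, so no positions are given. The 20046 genes comprise 13355 with 1 probe and 6691 with 2 or more, and each gene was represented by its probe with the highest mean log2 signal. A probe counted as detected at a detection p under 0.01. A gene was called by size when its log2 difference reached 1 in either direction and its probe was detected on the brighter array. Where a probe was detected on 1 array only, its fold is printed as a lower bound, the brighter signal over the higher of the dim probe's own signal and the lowest signal among detected probes of the dim array. Counts of genes and medians of lists use the normalized differences themselves.

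Before the data were examined, 27 gene lists and the rule for named genes were fixed. The rule takes TEAD4 with every probe, its family and cofactors, and the 12 highest and 12 lowest genes among those detected on both arrays and going the same way in the deposited normalized table. It adds the 4 highest and 4 lowest bounds among genes detected on 1 array, and up to 2 genes per list and direction past 1.5-fold. Placeholder symbols were skipped. Other genes are named as further examples and were chosen after their values were seen. For each list the median difference of the detected members was placed among the medians of 10000 random lists of the same size, matched in 20 bins of mean log2 signal. That percentile describes these 2 arrays and is not a p-value. No test between the groups was run, because 1 array per group leaves no estimate of the spread between cultures. No percentile was set in the plan as a threshold for calling a list.

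The spread between probes of one gene served as the only measure of technical error. Over 2497 genes with at least 2 probes detected on both arrays, the log2 differences of the 2 brightest probes had a standard deviation (SD) of 0.31 per probe, 0.27 in the brighter part and 0.34 in the dimmer part. The correlation between the probes across genes was 0.50, and genes are not independent replicates. Probes share the RNA, labelling and hybridization of their array, so this spread holds no difference between cultures or arrays. The scripts were tested on simulated data with that spread for the TEAD4 knockdown against the control. Of genes given a log2 change of 1, the threshold, 54% were called in the right direction, against 96% at 1.5 and 100% at 2. Each share is of a small set of changed genes in a run on 11305 genes. In that run 11 of 11080 unchanged genes were called. The simulation gave every probe the same SD and copied detection from the control array. No simulated gene was therefore detected on 1 array only. In the data dim probes spread more, and 3.60% of pairs differed by 1 or more. The 11 calls are thus no estimate of false calls among dim genes.

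Alternatives changed 1 choice at a time, apart from the deposited normalized table, which replaces the whole normalization, and the version without background correction, which also drops the offset and sets signals under 1 to 1. They were no normalization beyond median centring, no background correction, an offset of 50, the deposited normalized table, a detection p under 0.05, detection on both arrays, no detection filter, the mean of all probes or the median of the detected probes of a gene, thresholds of 1.5-fold and 3-fold, and 10 bins for the random lists. The median log2 difference of all detected genes was -0.04, and it lay between -0.04 and -0.02 under the other scalings. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Probes with several symbols or none were left out of all gene results.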

Results

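Expression was measured in SNU216, an established human gastric cancer cell line, on 1 array of control cells carrying a non-silencing short hairpin RNA and 1 array of cells with TEAD4 knocked down. TEAD4 is a DNA-binding transcription factor that works with the cofactors YAP and TAZ at the end of the Hippo pathway. Of 47323 probes, 18948 (40.0%) were detected on the control array and 18648 (39.4%) on the knockdown array, with 17476 detected on both. The detected probes covered 11720 genes on at least 1 array and 10717 on both. There were no replicates, so no difference given here has a replicate check, and the number of arrays limits the precision.

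The comparison asks which transcripts differ when TEAD4 is reduced. TEAD4 itself was 5.89-fold lower on the knockdown array by its brightest probe, ILMN_1705301, whose normalized log2 signal was 10.11 in the control and 7.55 in the knockdown (log2 difference -2.56). A dimmer TEAD4 probe, ILMN_2413041, was detected on the control array alone and was at least 1.17-fold lower, and the remaining probe, ILMN_1722824, was detected on neither array. The paralogs differed much less, with log2 differences of -0.23 for TEAD1, 0.05 for TEAD2 and -0.35 for TEAD3. Among the cofactors, YAP1 differed by -0.15, WWTR1, which encodes TAZ, by -0.13, VGLL1 by -0.48, VGLL3 by -0.29 and VGLL4 by -0.29, while VGLL2 was detected in the knockdown alone at a level at least 1.10-fold higher. Over the 10 TEAD family and cofactor genes, which include the targeted TEAD4, the median was -0.26, at percentile 7.77 of random lists matched on signal. Averaging the 3 TEAD4 probes, of which 1 was not detected, gave -1.22 in place of -2.56.

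By the size rule, 212 genes were at least 2-fold higher and 274 at least 2-fold lower in the knockdown, together 4.15% of the detected genes. The 12 highest and 12 lowest genes given next were ranked among genes detected on both arrays. Furthest up of these under the main normalization were PRSS22, a serine protease of epithelia, at 6.23-fold higher (2.64), and FSCN1, the actin-bundling protein fascin, at 6.13-fold higher (2.62). They were followed by GNG11, a G protein gamma subunit (2.28), BASP1, a membrane-attached signalling protein (2.27), STMN3, a stathmin that destabilizes microtubules (2.20), the ephrin receptor EPHA2 (2.10), SOCS2, a feedback inhibitor of cytokine signalling (1.92), and MMP9, a secreted gelatinase (1.87). ODAPH (1.81), SLC35G2 (1.80), the histone gene H2BC11 (1.79) and SPOCD1 (1.76) completed the 12 highest. The signal of PSG5, a pregnancy-specific glycoprotein otherwise made by the placenta, was 6.49-fold lower (-2.70), and that of its relative PSG9 was 4.49-fold lower (-2.17). Also among the 12 lowest were ACTG2, the smooth muscle gamma actin (-2.55), TNNC1, the troponin C of slow and cardiac muscle (-2.50), and TAGLN, which encodes the actin-binding transgelin (-1.94). The other lowest genes besides TEAD4 were the secreted factors EDN2 (endothelin 2, -2.43) and WNT5A (-2.35), the hyaluronan synthase HAS2 (-2.31), the transcription factors BACH2 (-2.07) and NPAS2 (-2.04), and the serpin SERPINB7 (-1.95).

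Several genes were detected on 1 array alone and have only a bound. IGFBP5, a binding protein of insulin-like growth factors, was at least 9.08-fold lower in the knockdown, and its other probe was at least 4.78-fold lower. KISS1, the precursor of the kisspeptins, was at least 5.24-fold lower, AXIN2, a feedback inhibitor and target of Wnt signalling, at least 3.81-fold lower, and the scavenger receptor SCARA3 at least 3.47-fold lower. In the other direction, the ubiquitin ligase TRIM6 was at least 5.05-fold higher, the noncoding SFTA1P at least 4.73-fold, the complexin CPLX1 at least 3.13-fold, and ANAPC7, a subunit of the anaphase-promoting complex, at least 2.49-fold. Of the 212 higher genes, 60 were detected on the knockdown array only, and of the 274 lower genes, 82 on the control array only.

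Of the genes at least 2-fold apart, 90 had another probe detected on the array where the gene was higher. The brightest such probe went the same way in 85 of these 90 genes (94.4%, 95% exact binomial interval 87.5 to 98.2%). That condition on detection favours the same direction among dim probes. The number of genes past 2-fold depends on the normalization: it was 486 here by both directions, 252 with an offset of 50 in place of 16, 182 in the deposited normalized table and 897 with neither background correction nor offset and signals under 1 set to 1. Without the correction, with values under 0 set to 0 and 16 added, it was 553. In the deposited table PRSS22 differed by 1.92, below FSCN1 (2.44), and H2BC11 by 1.17, ACTG2 by -1.60, EDN2 by -1.70, HAS2 by -1.58 and BACH2 by -1.42. PSG transcripts are near-identical to one another, so a value cannot be assigned with certainty to 1 such gene. The smooth muscle actin genes are paralogs too, and whether their probes share signal was not tested. The other 3 HAS2 probes were not detected. Second probes detected on both arrays gave -1.13 for TAGLN and -1.15 for BACH2. They gave -2.16 for PSG5, -2.02 for SERPINB7 and 1.88 for SOCS2.

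**Figure D1:**
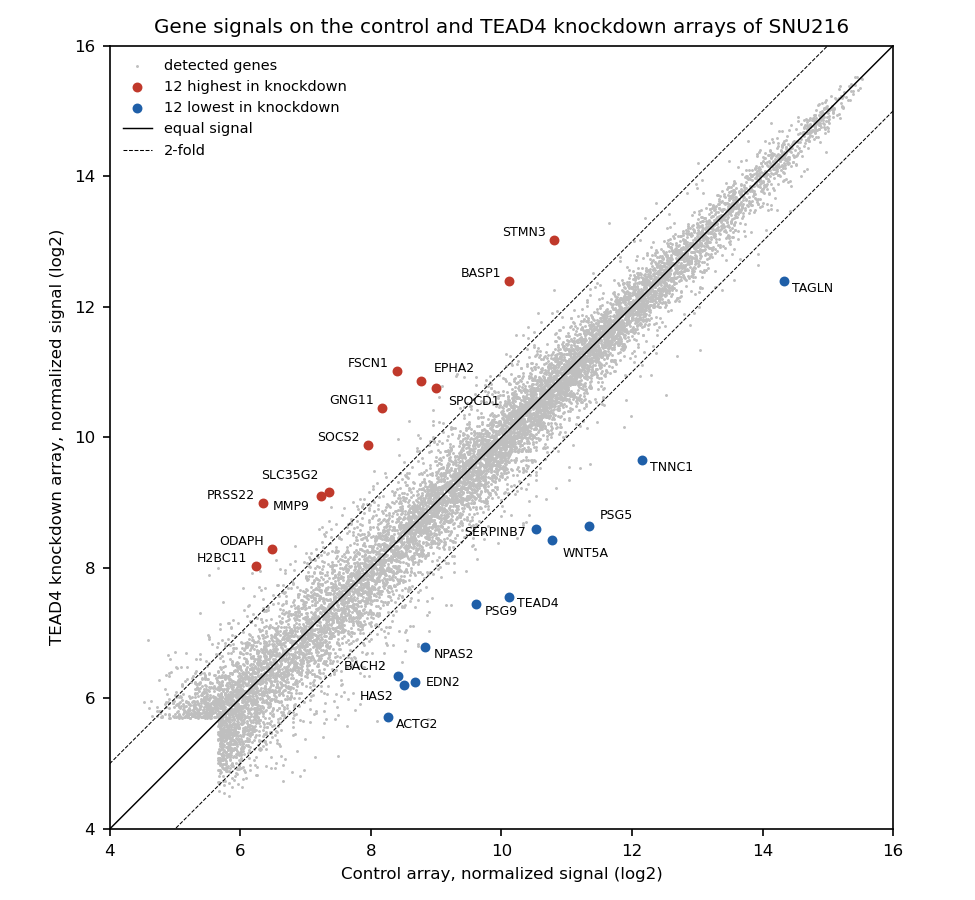
Normalized log2 signal of each detected gene on the control array (horizontal axis) and on the TEAD4 knockdown array (vertical axis), with 1 point per gene, a solid line of equal signal and dashed lines at 2-fold. The marked genes are the 12 highest and 12 lowest among those detected on both arrays. The 12 highest, from SPOCD1 (1.76) to PRSS22 (2.64), lie above the upper dashed line, and the 12 lowest, from TAGLN (-1.94) to PSG5 (-2.70), lie below the lower one.

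Inflammatory genes driven by the transcription factor NF-kB were higher in the knockdown as a group. Of 21 detected members, 13 were at least 1.5-fold higher and 1 was at least 1.5-fold lower, with a median of 0.85. All 10000 random lists had a lower median (percentile 100). The neutrophil-attracting chemokines CXCL1 (1.65) and CXCL8 (1.63) differed most, followed by the cytokine IL6 (1.30) and the chemokine CCL20 (1.26), and the inhibitor NFKBIA was 1.56-fold higher (0.65). IL18, another cytokine, was the exception past 1.5-fold (-0.59). The list's median ranged from 0.45 to 0.91 over the alternatives, with percentile 100 under each, and it was 0.65 with members detected on 1 array set to their bounds.

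Genes of the unfolded protein and integrated stress responses were lower as a group. Of 24 detected members, 8 were at least 1.5-fold lower and 0 were higher by that much, with a median of -0.35 at percentile 0. The largest differences were in ASNS, the asparagine synthetase (-1.66), and DNAJB9, a chaperone of the endoplasmic reticulum (-1.62). PHGDH, the first enzyme of serine synthesis (-1.08), and DDIT3, the stress transcription factor CHOP (-0.82), were lower as well, whereas the transcript of the regulator ATF4 differed by -0.34 and that of CEBPB by 0.10.

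Wnt pathway and target genes had a median of -0.38 at percentile 0.13, with 6 of 14 detected members at least 1.5-fold lower and 1 higher. WNT5A and AXIN2 were named above, the receptor FZD7 differed by -0.96, and CTNNB1, which encodes beta-catenin, was the member that was higher (0.95). With the members limited to those detected on both arrays, a filter that drops members such as AXIN2 for being low in the knockdown, the median was -0.17 at percentile 8.06, and without a detection filter it was -0.14 at percentile 2.31.

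Hypoxia and glycolysis genes had a median of 0.17 at percentile 99.6, with 3 of 25 detected members at least 1.5-fold higher and 2 lower. The glycolytic enzymes PGK1 (0.90) and TPI1 (0.76) were the highest, and the peptide hormone ADM (-0.96) and the enolase ENO2 (-1.001) went the other way, as did VEGFA (-0.37). Interferon-stimulated genes had a median of 0.18 at percentile 99.8, with 4 of 30 detected members at least 1.5-fold higher and 3 lower. PSMB9, an immunoproteasome subunit (1.24), and the transcription factor IRF1 (0.95) were the highest, while the antiviral genes OAS2 (-1.65, or -1.01 in the deposited table) and IFIT1 (-1.04) were lower, and BST2 was at least 1.43-fold lower. Another PSMB9 probe differed by 0.06. Heat shock and chaperone genes had a median of 0.13 at percentile 98.0, with 1 of 16 detected members past 1.5-fold, DNAJB4, at least 1.20-fold higher. Averaging the probes of each gene brought that median to 0.04 at percentile 74.4.

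**Figure D2:**
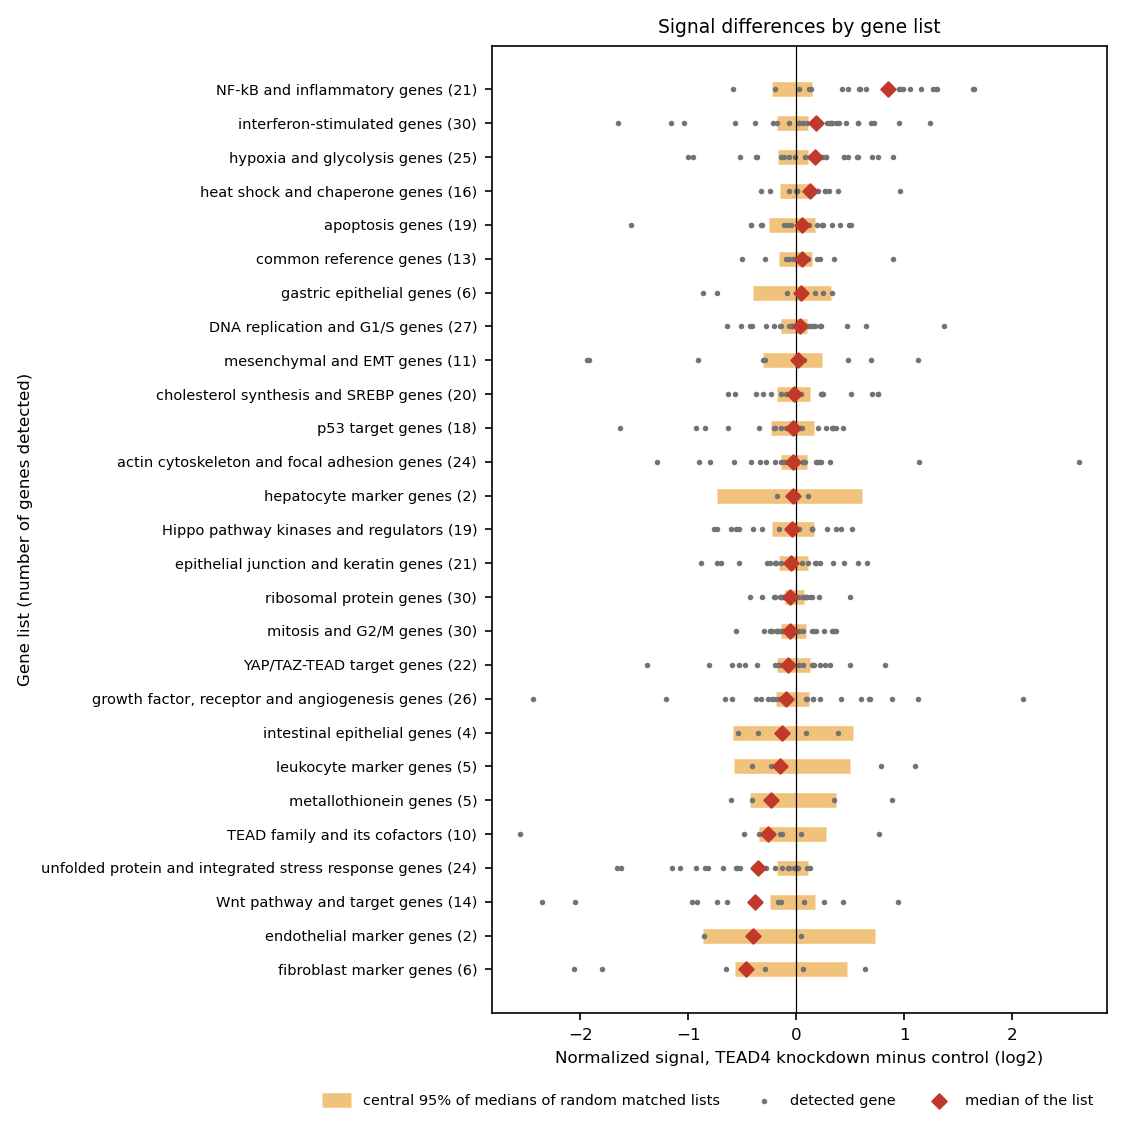
Log2 difference, knockdown minus control, for the detected genes of each fixed list (grey points, numbers of genes in brackets), the list's median (red diamond) and the central 95% of the medians of 10000 random lists matched on signal (bar). The NF-kB list has the highest median (0.85), and the medians of the stress response list (-0.35) and the Wnt list (-0.38) lie left of their bars.

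Known target genes of YAP, TAZ and the TEAD factors did not stand apart as a group, with a median of -0.08 over 22 detected genes at percentile 24.5. The common readouts CCN1 (0.16), CCN2 (0.07), ANKRD1 (-0.09) and AXL (0.16) were near equal on the arrays. At least 1.5-fold lower were 3 members, among them RBMS3 (-1.38) and GADD45B (-0.81), and 1 was higher, the ectonucleotidase NT5E (0.82). Another RBMS3 probe detected on both arrays differed by -0.55, which is under 1.5-fold. Hippo pathway kinases and regulators had a median of -0.04 over 19 genes at percentile 47.4, with 3 members at least 1.5-fold lower, including the kinase STK3 (-0.73) and the atypical cadherin FAT4 (at least 1.33-fold lower).

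Proliferation genes showed no shift beyond the random lists. Genes of DNA replication and the G1/S step had a median of 0.03 over 27 genes at percentile 80.8, in which the ribonucleotide reductase subunit RRM2 (1.37) and E2F1 (0.65) were at least 1.5-fold higher and the cyclin CCND1 (-0.64) lower. None of the 30 mitosis and G2/M genes was 1.5-fold apart, and their median was -0.06 at percentile 24.4. The p53 target genes had a median of -0.03 over 18 genes at percentile 54.1, with 4 members lower, including the secreted factor GDF15 (-1.64) and SESN2 (-0.92), and 0 higher. Apoptosis genes had a median of 0.05 and a mean of -0.03 over 19 genes at percentile 79.1, with the pro-apoptotic HRK at least 1.80-fold lower.

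Epithelial and mesenchymal genes went both ways. Epithelial junction and keratin genes had a median of -0.05 over 21 genes at percentile 34.1: the adhesion molecule CDH1 was higher (0.66), and the keratin KRT7 (-0.73) and the tight junction protein CLDN1 (-0.88) were lower. Mesenchymal genes had a median of 0.02 and a mean of -0.26 over 11 genes at percentile 67.8, since the transcription factor SNAI2 (1.12) and the intermediate filament VIM (0.69) were higher and the smooth muscle genes ACTA2 (-1.92) and TAGLN lower. Actin cytoskeleton and focal adhesion genes had a median of -0.03 over 24 genes at percentile 40.1, with FSCN1 and the laminin chain LAMB3 (1.14) higher and the myosin light chain MYL9 (-0.90) and the caldesmon gene CALD1 (-1.29) lower. A dimmer MYL9 probe differed by 0.19, and of the other CALD1 probes 1 differed by -1.39 and the dimmest by -0.07. Growth factor, receptor and angiogenesis genes had a median of -0.10 and a mean of 0.01 over 26 genes at percentile 22.1, with 6 members at least 1.5-fold higher and 4 lower. EPHA2 and the growth factor HBEGF (1.13) were the highest of these, and EDN2 and the ribonuclease ANG (-1.20) the lowest.

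Few genes of differentiated stomach or gut were detected. The 6 detected gastric epithelial genes had a median of 0.04 and a mean of -0.16 at percentile 67.6, with AGR2, a disulfide isomerase of mucus-producing cells, lower (-0.86) and AGR3 at least 1.46-fold lower. The 4 detected intestinal genes had a median of -0.13 at percentile 39.6. Cholesterol synthesis genes had a median of -0.03 and a mean of 0.06 over 20 genes at percentile 49.4, with the enzymes EBP (0.75) and MVK (0.75) higher and the regulator SREBF2 (-0.64) lower. The 5 detected metallothionein genes had a median of -0.23 at percentile 14.6, with MT1X higher (0.88) and MT1F lower (-0.60). Ribosomal protein genes had a median of -0.06 over 30 genes at percentile 12.2, with 0 past 1.5-fold, and common reference genes a median of 0.05 over 13 genes at percentile 78.9, with PGK1 alone past 1.5-fold.

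Markers of other cell types were mostly not detected. Of the fibroblast markers 6 were detected, with a median of -0.47 at percentile 5.60. The matrix proteins FBLN1 (-1.80) and LUM (at least 2.41-fold lower) were lower, and the collagen COL6A3 was at least 1.14-fold higher. Another FBLN1 probe detected on both arrays differed by -0.94. The 5 detected leukocyte markers had a median of -0.15 and a mean of 0.22 at percentile 34.3, with the lysosomal protein CD68 higher (1.10) and MS4A1 at least 1.04-fold higher. The 2 detected endothelial markers had a median of -0.41 at percentile 15.8, with ESAM lower (-0.85), and the 2 detected hepatocyte markers a median of -0.03 at percentile 51.6. The medians of the Hippo, DNA replication, mitosis, mesenchymal, actin, gastric, intestinal, p53, cholesterol, leukocyte and hepatocyte lists changed sign under at least 1 alternative and stayed inside the random range. With members detected on 1 array set to their bounds, the median was -0.28 for the fibroblast, -0.11 for the leukocyte, -0.02 for the intestinal, -0.02 for the gastric, -0.09 for the growth factor, -0.33 for the stress response and -0.26 for the Wnt list, so that the gastric sign turned.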

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

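The test of single-probe noise reported here was set before its result was seen, while the count of unlisted probes was not part of the plan and was chosen after the data had been seen.

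Probes that the platform annotation does not list carried signal that the gene results leave out. Of 17202 such probes, 4924 were detected on at least 1 array, and 139 were detected on the knockdown array and at least 2-fold above the control array, with 86 lower by that much. Together these are 4.57% of the detected unlisted probes, against 4.75% of the detected probes with 1 gene symbol.

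Genes past 2-fold were more frequent among dim genes, with 233, 150, 76 and 27 genes from the dimmest to the brightest of 4 groups of 2930 genes each, and noise of single probes is a candidate explanation. In the brighter part of the called genes, another detected probe went the same way in 96.6% of 59 genes (95% exact binomial interval 88.3 to 99.6%), above the 75% that had been set as the bound against noise. In the dimmer part it did so in 90.3% of 31 genes (74.2 to 98.0%), an interval that excludes 50% but not the bound of 75%. The other probe had to be detected on the array where the called gene was higher. Noise alone could therefore give more than 50% among dim probes, so noise in part of the dim calls stays open. Genes with a single detected probe were not covered. Probes of one array share its RNA and hybridization, so these shares say nothing on differences between cultures, handling or arrays, which cannot be told apart from the knockdown with 1 array per group.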

How the results depend on the processing

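One alternative was chosen after seeing the data, the deposited signals plus 16 without further background correction; it gave 236 genes higher and 317 lower, 553 in all, within 1.5 times the 212 and 274 of the main setting. No paired analysis was possible because each group has 1 array, which also rules out leaving out a replicate. The alternative with bead standard errors was not run, since no such errors were used here. Differences were called moved past the SD per probe (0.31) for genes and the SD of random medians for lists, tolerances chosen after the data were seen. None of the 12 highest and 12 lowest genes, nor of the examples picked by rule from the lists, changed sign under these settings. For the 12 highest and 12 lowest, the selection had required the same direction in the deposited normalized table. The detection settings do not alter a gene's value, so its sign could not turn there. The NF-kB, stress response, Wnt, hypoxia, interferon and heat shock medians kept their sign too, while the list medians named at the end of the results did not. Of the list medians 278 stayed within the tolerance and 19 moved, and of the named genes' values 754 stayed and 76 moved.

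Counts of 2-fold genes (higher, lower, both) became 394, 503 and 897 with neither background correction nor offset and signals under 1 set to 1, 105, 147 and 252 with an offset of 50, and 77, 105 and 182 in the deposited normalized table. They were 848, 1078 and 1926 at 1.5-fold and 28, 60 and 88 at 3-fold, by construction. All 77 and 105 genes of the deposited table were among the 212 and 274, as were all 105 and 147 genes with an offset of 50. The deposited table keeps each array's rank order and lies above the non-normalized signals by a median of 100.7, which shrinks folds. Its nesting is therefore no independent check. TEAD4 differed by -2.36 with an offset of 50 and by -2.22 in the deposited table. Smaller folds go with a larger added constant, but how far this accounts for the deposited TEAD4 value was not tested. TEAD4 differed by -1.22 as the mean of its probes and by -1.81 as the median of detected probes, which take in dimmer probes with smaller differences.

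The NF-kB median was 0.64 with an offset of 50, 0.60 in the deposited table, 0.65 at a detection p under 0.05, 0.45 without a detection filter, 0.58 with the mean of probes and 0.65 with the median of detected probes. The gastric median was -0.14 at a detection p under 0.05. The Wnt median was -0.17 with detection on both arrays and -0.14 without a filter. Without a filter the DNA replication median was -0.035 and the fibroblast median -0.17. With the mean of probes the medians were 0.0060 for mitosis, -0.14 for mesenchymal, 0.088 for cholesterol, 0.044 for heat shock, -0.0055 for ribosomal protein and 0.13 for reference genes. With the median of detected probes mitosis had 0.0060 and reference genes 0.13. The cause of these list changes was not tested. Signal over background limits folds of dim probes.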

Other observations

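The leukocyte test was chosen after the result was seen, as were the gene families, the PSG pattern, the added condition on its interval and its ratio over probes detected on both arrays, while the other tests here were set before their values were known.

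Among 8 gene families picked by symbol, histone genes stood highest relative to random lists: 18 of 36 detected members were at least 1.5-fold higher and 1 lower, with a median of 0.55 at percentile 100, led by H2BC11 (1.79) and H3C8 (1.57). The family pools replication-dependent and other histone genes. Its brightest members, H2AZ1 (-0.21) and H3-3A (-0.02), were not higher, while the next in signal, H4C3 (0.76) and H2BC12 (0.87), were. Of 14 detected keratin genes, 7 were at least 1.5-fold lower and 0 higher, with a median of -0.47 at percentile 0.150, including KRT13 (-1.52) and KRT15 (-1.50). Among the 7, KRT3 and KRT83 were detected on the control array only. The brightest keratins, KRT8 (-0.14), KRT19 (-0.04), KRT80 (-0.31) and KRT10 (0.02), were each under 1.5-fold, so the shift lay in dimmer keratins. The 3 detected chorionic gonadotropin beta genes had a median of 1.36 at percentile 99.98, with CGB5 at 1.54. Mitochondrial ribosomal protein genes had a median of 0.10 over 73 genes at percentile 99.9 and proteasome subunit genes 0.10 over 33 genes at percentile 98.7, while serpin clade B, S100 and claudin genes were at percentiles 46.6, 86.4 and 78.2. Each family median kept its sign under the 6 scalings run, from 0.45 to 0.58 for histones, -0.66 to -0.28 for keratins and 0.83 to 1.58 for the gonadotropin genes. Some histone, keratin and gonadotropin genes are close paralogs, whose probes can share signal.

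All 14 PSG probes detected on the control array were lower in the knockdown, 12 of them at least 2-fold, with a median of -1.43 and a range from -2.70 to -0.17 (PSG7). A technical reading is that every probe reports 1 shared transcript, which would leave no more spread than probes of one gene show. The SD over the 14 probes was 0.68, against 0.31 between probes of one gene, a ratio of 2.16 (95% interval 1.57 to 3.48). The interval treats the probes as independent and the reference SD as known, although the 14 probes cover 9 genes. That reference took all pairs within the signal range of the PSG probes, 2367 of 2497, so it was hardly matched on brightness. The dimmer part of all pairs had an SD of 0.34, which would lower the ratio. Over the 12 PSG probes detected on both arrays, as the reference probes are, the ratio was 2.21 (1.57 to 3.76). Both intervals exclude a spread equal to that reference. They hold the ratio of 2 set beforehand as the bound against a shared transcript. The condition that the interval lie above 1 was added after the ratio had been seen. The reference pairs were also not chosen for large differences. Probes of one strongly lowered gene can lie further apart, as for TAGLN (-1.94 and -1.13) and BACH2 (-2.07 and -1.15). Those of SERPINB7 did not (-1.95 and -2.02). The comparison therefore cannot decide for or against a single shared transcript. A single shared transcript and partial sharing of signal between PSG probes stay open, and so does any cause outside the knockdown.

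The higher signal of the NF-kB list may extend to NF-kB target genes in general, as a hypothesis. A further list of 30 target genes held 0 genes of any fixed list. Its median was 0.33 over 26 detected genes, at percentile 100. Of the 26, 22 were above 0, 9 were at least 1.5-fold higher and 2 at least 1.5-fold lower. Leukocytes in the knockdown culture would bring their abundant transcripts, but 0 of 4 (PTPRC, TYROBP, FCER1G and LYZ) were detected there at least 1.5-fold higher: PTPRC, TYROBP and FCER1G were detected on neither array, and LYZ had log2 signals of 6.10 and 5.94. In the fixed leukocyte list, however, 2 of 5 detected markers were at least 1.5-fold higher by normalized signal: CD68, a lysosomal protein not limited to leukocytes, by 2.15-fold (1.10, with another detected probe at 0.66), and MS4A1, whose bound is at least 1.04-fold higher. Whether the shift follows from lower TEAD4, from the hairpin or from the state of 1 culture cannot be separated here.

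The lower signal of the stress response list could reflect lower activity of ATF4, as a hypothesis. The cytosolic aminoacyl-tRNA synthetase genes, other ATF4 targets, had a median of -0.13 over 12 detected genes at percentile 10.5, with 10 below 0 and 0 past 1.5-fold. This lies between the bounds set for and against the hypothesis, so the test did not decide it.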
